A study of Mus musculus with 4 samples.

How the data were processed

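RNA from 4 preparations of BALB/c mouse mast cells was measured on Affymetrix whole-transcript arrays, with 1 array for each group. Per the labels' protocols, bone marrow-derived mast cells (BMMCs) were grown from bone marrow for 3 to 4 weeks with interleukin-3 and stem cell factor, each at 10 ng/ml. They then spent 6 days in plain medium (control), with TGF-beta1 at 5 ng/ml, or with Chinese hamster ovary (CHO) cells that expressed the mouse Notch ligand Dll1. The labels state that cells from the Dll1 coculture were selected with magnetic beads for c-Kit. The intestinal mast cells came from the lamina propria of the small intestine of untreated mice and were sorted by flow cytometry as positive for FceRI and c-Kit. No selection step is named for the control and TGF-beta1 cultures. Labelled cDNA was amplified from 2 ng of RNA with a kit for very small inputs, per the labels' protocols.

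The deposited table held log2 values of 33793 probe sets, between 4.13 and 13.14. The software that summarised the probes, the normalization and the genome build are not given in the sources used here. The sorted values of the 4 arrays differed by 0.06 on average and by at most 0.25, so the arrays had been brought to nearly the same distribution before deposit. No further normalization was applied. The log2 values had a floor just above 4, which compresses the differences of dim genes. The highest value of each array lay between 13.00 and 13.14, and whether the brightest probe sets were saturated is not known. An array gives no read depth, and the number of arrays limits the precision.

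Gene symbols came from the platform annotation. A single symbol was given for 23521 probe sets, several symbols for 1814, and 8458 were not listed there. Only probe sets with 1 symbol were used for named genes, which gave 22180 genes. Where a gene had more than 1 probe set, as 1082 genes did, the one with the highest mean over the 4 arrays was used. Neighbouring genes and gene order were taken from the RefSeq table of GRCm38.p6, with no coordinates.

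A background limit was set on each array as the 95th percentile of 1440 probe sets of olfactory, vomeronasal and taste receptor genes. It was 5.11 on the control array, 5.20 on the TGF-beta array, 5.12 on the Dll1 array and 5.11 on the intestinal array. A gene was said to differ when it was above the limit on at least 1 of the arrays compared and the difference was at least 2-fold, with a value under the limit raised to it. Where a gene was above the limit on 1 array alone, its fold is a bound, printed as "at least". With 1 array per group there was no replicate error, so no p-value was computed.

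The main comparisons were TGF-beta minus control, Dll1 minus control, intestinal minus control and Dll1 minus TGF-beta. For 41 gene lists, the median log2 difference was placed among 10000 random lists of the same size, matched on mean value in 20 bins. That percentile describes these arrays and carries no error between samples. List medians used the measured values of all members, those below background included. The rule for named genes took 19 genes on every array. For each comparison it added the 8 highest and the 8 lowest differences measured on both arrays and the 4 largest bounds in each direction, leaving out by symbol predicted genes, microRNAs, small nucleolar and nuclear RNAs and receptor segments, but not other small RNAs such as Rny3. It also took up to 4 members of each list with the largest differences. The comparisons, these lists and the rule were fixed before the data were examined, as were the alternative settings, apart from leaving out the handling, feeder and other-cell lists from the counts and subtracting an offset of 16.

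As a gauge of technical spread, genes with 2 probe sets above background were used. The standard deviation between the log2 differences of such probe sets was 0.24 for TGF-beta minus control, 0.34 for Dll1 minus control, 0.48 for intestinal minus control and 0.34 for Dll1 minus TGF-beta. It covers no variation between cultures or animals. The size rule was tested on simulated data in which 200 of 22180 genes were changed by 3 on the log2 scale, at levels where the change stayed above background. All 200 were recovered in each of the 4 comparisons (100%). At a change of 1.5, the shares recovered were 95.0% for TGF-beta minus control, 93.5% for Dll1 minus control, 84.5% for intestinal minus control and 95.0% for Dll1 minus TGF-beta. The simulated noise was normally distributed. Its width came from the median absolute deviation of the observed differences, over genes above background on both arrays. With a change of 1.5, the rule also called 0, 26, 271 and 13 unchanged genes, in the same order. Such noise leaves out wide tails, so these numbers are no upper limit on false calls. Of 200 simulated random lists, 6.5% fell outside the middle 95%.

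The alternatives were array medians subtracted, quantile normalization repeated, another background percentile or no limit, the mean of a gene's probe sets, and thresholds of 4-fold and 1.5-fold. For lists, unmatched random lists and members above background were tried. For correlations, rank correlation, all genes, and leaving out lists were tried. Probe sets without a single symbol were left out of the named results. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.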

Results

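Expression was measured in 4 groups of mouse mast cells with 1 array each, so no value below has a replicate check. The groups were control BMMCs, BMMCs kept for 6 days with TGF-beta1, BMMCs cocultured for 6 days with CHO cells carrying the Notch ligand Dll1, and mast cells sorted from the small intestine. TGF-beta1 is a cytokine and Dll1 is a membrane ligand of Notch receptors. Of 22180 genes, 11711 were above background on the control array, 11304 on the TGF-beta array, 12370 on the Dll1 array and 12139 on the intestinal array. Levels are log2 values and are compared within a gene between arrays, never between genes.

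The chymases Mcpt1 and Mcpt2, granule proteases of mucosal mast cells, were low on the control array and high on the other 3. Mcpt1 read 4.82 in control BMMCs, below background, 12.41 with TGF-beta1, 12.46 with Dll1 and 12.72 in intestinal mast cells. Mcpt2 read 5.75, 12.35, 11.74 and 12.33 in the same order. Mcpt4, a chymase of connective tissue mast cells, was below background in control (4.53) and TGF-beta1-treated BMMCs (5.04) but read 10.15 with Dll1 and 10.41 in intestinal cells. Mcpt8, a protease counted here among the basophil markers, read 8.50, 7.68, 10.89 and 10.94. Whether basophils contributed to it was not tested. Cma1 (mast cell protease 5) was near 12 in control BMMCs (12.12) and with TGF-beta1 (11.98), 11.37 with Dll1 and 7.16 in intestinal cells. The tryptase Tpsb2 read 11.55, 11.78, 11.83 and 6.21, and the tryptase Tpsab1 read 8.25, 11.81, 10.05 and 5.26. Carboxypeptidase Cpa3 read between 12.76 and 13.11 on the 4 arrays, at or near the highest value of each, where a difference can be hidden by saturation.

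The integrin chain Itgae, which pairs with Itgb7 on mucosal lymphocytes and mast cells, read 5.57 in control BMMCs, 8.84 with TGF-beta1, 7.97 with Dll1 and 11.28 in intestinal cells. Itgb7 read 8.68, 9.27, 9.66 and 9.62. The receptor genes that define mast cells were far above background on every array, with Kit at 12.65, 12.22, 12.54 and 11.75, Fcer1a at 12.41, 12.40, 12.39 and 11.66, and Ms4a2 at 10.85, 10.67, 10.42 and 9.98. Among Notch genes, Hes1 read 6.03, 5.85, 7.01 and 7.51. Hey1 was below background on the 3 BMMC arrays (4.99, 5.16 and 4.76) and read 9.71 in intestinal cells. Notch1 read 6.25, 6.43, 6.25 and 7.78, while Notch2 stayed between 10.14 and 10.42. Smad7, an inhibitor of TGF-beta signalling, read 7.42, 8.01, 8.01 and 9.27. Dll1 itself was above background on the Dll1 array alone (7.10, against 4.79, 4.70 and 4.88), and its second probe set read 5.13 there. The feeder cells of that culture expressed Dll1, and their RNA was not told apart from that of the mast cells.

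**Figure D1:**
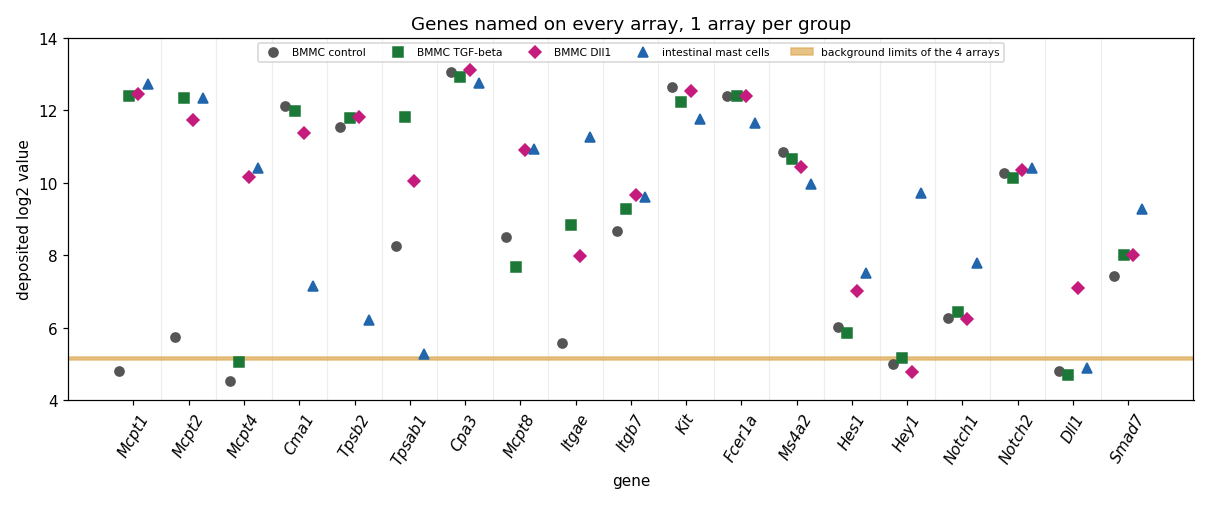
Deposited log2 values (vertical axis) of the 19 genes named on every array (horizontal axis), with 1 symbol per array and a band for the background limits of the 4 arrays. Mcpt1 lies at 4.82 on the control array and between 12.41 and 12.72 on the others, while Mcpt4 is above the band on the Dll1 and intestinal arrays alone.

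The comparison of TGF-beta1-treated with control BMMCs asked what this cytokine did to cultured mast cells. Mcpt1 was at least 157-fold higher and Mcpt2 was 97.1-fold higher with TGF-beta1. Tpsab1 was 11.8-fold, Itgae 9.61-fold, Plac8 8.14-fold and the inflammasome sensor Nlrp6 7.63-fold higher. The pseudogene Mcpt-ps1 was 5.12-fold, the fatty acid desaturase Scd1 3.95-fold and the adaptor Sh2d1b1 3.77-fold higher. The receptor Mrgpra9 was at least 9.15-fold, the lysophospholipid transporter Mfsd2a at least 7.53-fold and the laminin-binding integrin Itga7 at least 5.05-fold higher. Lower with TGF-beta1 were Asphd2 (5.84-fold), the protease inhibitor Serpinb2 (5.58-fold), the calcium-binding proteins S100a6 (5.26-fold) and S100a4 (4.73-fold), the sodium pump subunit Atp1b1 (4.63-fold), Cyp4a12a (4.36-fold), the glycolipid enzyme A4galt (3.94-fold) and Ndrg1 (3.75-fold). The serotonin transporter Slc6a4 was at least 5.24-fold lower, the elastase Mmp12 at least 4.61-fold, the complement regulator Cd59a at least 4.09-fold and Dse, an enzyme of dermatan sulfate synthesis, at least 2.95-fold.

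Of 7 mucosal mast cell genes, Mcpt1, Mcpt2 and Itgae were at least 2-fold higher and none was lower, with a list median of 0.59 (log2; 100th percentile). Among 29 measured TGF-beta target genes, 4 were higher, among them Itgae, Ldlrad4 (1.81) and Gadd45b (1.34). Id2 was lower, by -1.88, and the list median was 0.08 (96.95th percentile). The 38 cell cycle genes had a median of 0.53 and the 19 cholesterol synthesis genes one of 0.44, both at the 100th percentile. Tyms (1.14) was the 1 cell cycle gene at least 2-fold higher, and no cholesterol gene was. Cyp51 was 0.81 and Hsd17b7 0.75 higher. Oxidative phosphorylation (0.20), cytosolic ribosomal protein (0.27) and unfolded protein response genes (0.20) also lay at the 100th percentile, with no member past 2-fold. Glycolysis and hypoxia genes had a median of -0.26 (0.01st percentile), FceRI signalling genes -0.24 (0.26th) and basophil markers -0.46, below all random lists. Notch target genes had a median of 0.13 at the 98.65th percentile, and no member was 2-fold higher or lower. Over members above background the median was 0.089 at the 90.9th percentile, and quantile normalization or the mean of a gene's probe sets gave the 97.19th.

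In all, 61 genes were at least 2-fold higher and 107 lower among 12063 tested, and 12 and 9 passed 4-fold. With an offset of 16 subtracted on the linear scale, an alternative chosen after the data were seen, 111 were higher and 184 lower. The 2 arrays correlated at r = 0.99 across genes, which are not independent replicates. Near-identical family members, such as the Mcpt genes, can share probes, so their separate levels are uncertain.

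The comparison of Dll1-cocultured with control BMMCs asked what a Notch ligand did. Mcpt1 was at least 163-fold, Mcpt2 63.7-fold and Mcpt4 at least 32.9-fold higher on the Dll1 array. Among genes of eosinophil granules, Prg2 (major basic protein) was 66-fold, its relative Prg3 at least 21.7-fold and the peroxidase Epx at least 13.1-fold higher. The stress-responsive genes Dusp1 (31.4-fold), Egr1 (28.6-fold), Nr4a1 (23.7-fold) and Fosb (23.2-fold) stood beside them. The surface protein Cd7 was 26-fold, the MHC class II chain H2-Ea at least 15.3-fold and the protease Ctsg (cathepsin G) 9.79-fold higher. Lower with Dll1 were the interferon-induced GTPase Gbp4 (12.1-fold), the retroviral gene Erv3 (11.5-fold), the receptor Mrgpra4 (8.52-fold), the long noncoding RNA Neat1 (7.87-fold), Efcc1 (5.46-fold), Slc6a4 (5.39-fold), Nrn1 (5.15-fold) and the betaine transporter Slc6a12 (4.64-fold). Usp17le was at least 9.22-fold lower, the coagulation factor subunit F13a1 at least 5.68-fold, Mab21l2 at least 4.36-fold and Kcnab3 at least 3.44-fold. A second probe set of Kcnab3 was below background on both arrays (5.05 in control and 4.90 with Dll1).

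Of the 7 mucosal mast cell genes, Mcpt1, Mcpt2 and Itgae (2.40) were higher, with a median of 0.99 (100th percentile). Among 11 connective tissue mast cell genes, Mcpt4 and Tpsab1 (1.81) were higher and Mrgpra4 (-3.09) was lower. The TGF-beta target list had 4 of 29 members higher, Junb (2.71), Itgae, Gadd45b (1.20) and Cdkn2b (1.05), with a median of 0.22 (99.96th percentile). Junb and Gadd45b also belong to the immediate early list. Notch target genes had 1 of 20 higher, Il2ra (1.10), and a median of 0.15 (95.68th percentile), with Hes1 0.97 higher. That percentile depended on the setting, with the 97.73rd over members above background (median 0.21), the 99.2nd against unmatched random lists and the 80.3rd with the mean of a gene's probe sets. Immediate early genes, which respond within minutes to handling or stimulation, were higher for 13 of 30 members, with a median of 0.82 (100th percentile). Of 7 eosinophil markers, Prg2, Prg3, Epx and Alox15 (1.99) were higher, with a median of 1.99. Of the others, the surface receptors Siglecf and Il5ra were below background on both arrays, and Ccr3 differed by -0.34. Of 14 neutrophil markers, 5 were higher, among them S100a8 (at least 13.4-fold), Elane (at least 12.5-fold), Ngp (at least 6.77-fold) and Mpo (2.83), and 1 was lower, with a median of 0.86 (100th percentile). MHC class II genes were higher for 4 of 13, with H2-Eb1 2.81 and H2-Ab1 2.73.

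Cholesterol synthesis genes were lower for 7 of 19, with a median of -0.97, below all random lists. Insig1 was lower by -1.54, Lss by -1.40, Hmgcs1 by -1.29 and Tm7sf2 by -1.25. Cell cycle genes had a median of -0.31 (0.01st percentile), with E2f8 (-1.79), Mki67 (-1.73) and Prc1 (-1.15) past 2-fold. FceRI signalling genes had a median of -0.41, below all random lists, with no member past 2-fold. Of 29 genes of adherent cells, listed as a gauge of RNA carried over from the feeder line, 4 were higher, Dll1 (at least 3.96-fold), Actn1 (1.97), Anxa2 (1.78) and Thbs1 (at least 2.13-fold), and the median was 0.35 (100th percentile).

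In all, 209 genes were at least 2-fold higher and 228 lower among 12806 tested, a higher share of 47.8%. With array medians subtracted the numbers were 172 and 322, a share of 34.8%, after quantile normalization 216 and 211, and with the offset of 16 subtracted 360 and 394. Coculture with hamster cells and bead selection went with Dll1 on this array and cannot be separated from it.

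The comparison of intestinal mast cells with control BMMCs asked how tissue mucosal mast cells differed from cultured ones. Mcpt1 was at least 196-fold, Mcpt2 95.8-fold, Itgae 52.2-fold and Mcpt4 at least 39.3-fold higher in intestinal cells. The heat shock genes Hspa1a (at least 101-fold) and Hspa1b (at least 79.3-fold), the integrin Itgax (CD11c, at least 67.6-fold), Nr4a1 (85-fold), Dusp1 (58.5-fold), Fosb (54.1-fold), Egr1 (33.1-fold) and Zfp36 (31.7-fold) were higher as well. The atypical chemokine receptor Ccrl2 was 24.6-fold and Hey1 at least 24.2-fold higher. Lower were Tpsb2 (40.6-fold), Mrgpra4 (31.4-fold), Cma1 (31.1-fold), the Y RNA Rny3 (29.1-fold), Arhgap20 (24.5-fold), the adhesion molecules Cadm1 (23.4-fold) and Cadm3 (20.7-fold), and Gpm6a (22.5-fold). Erv3 was at least 32.1-fold lower, the complement regulator Cd55 at least 24.6-fold, the phosphatase Ptprg at least 23.4-fold and Igfbp5 at least 22.6-fold.

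Of 7 mucosal mast cell genes, 3 were higher and 1 was lower, with a median of 0.94 (100th percentile). Of 11 connective tissue mast cell genes, Mcpt4 and Mcpt9 (at least 3.92-fold) were higher and 5 were lower, among them Tpsb2, Mrgpra4 and Cma1. The median of that list was -0.75, below all random lists. Of 23 mast cell core genes, 7 were lower and none higher, with a median of -0.63. Cyp11a1 was lower by -1.94, the adenosine receptor Adora3 by -1.82, the amine transporter Slc18a2 by -1.77 and the transcription factor Gata1 by -1.62. FceRI signalling genes had 5 of 19 lower and 1 higher, with Pik3cd at -2.21 and Fyn at 1.47, and the median of -0.37 lay at the 2.41st percentile, or the 2.93rd with the mean of a gene's probe sets. Notch target genes had 3 of 20 higher, Hey1, Notch1 (1.53) and Hes1 (1.48), and Hey2 was at least 3.31-fold lower, with a median of 0.24 (99.67th percentile). TGF-beta target genes had 9 of 29 higher and 3 lower, with a median of 0.34 (99.99th percentile). Among the higher ones were Itgae, Ldlrad4 (3.93), Junb (3.44) and Gadd45b (3.11), of which Junb and Gadd45b are also in the immediate early list. Unfolded protein response genes were higher for 7 of 22, with Hspa5 at 2.61, Ddit3 at 1.92, Dnajb9 at 1.65 and Herpud1 at 1.62. MHC class II genes were higher for 6 of 13, with H2-Ab1 at 2.78 and H2-Eb1 at 2.46. Among cytokine and chemokine genes 10 of 33 were higher, with Ccl4 at 3.61, Ccl5 at 3.45 and Tnf at 3.22, and 4 were lower, with Ccl2 at -3.47. Glycolysis and hypoxia genes had 5 of 24 lower, with Aldoc at -3.20 and a median of -0.51. Cell cycle genes had 5 of 38 higher and none lower, with a median of 0.40 (100th percentile).

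Immediate early genes were higher for 28 of 30 members on the intestinal array, with a median of 3.28 (100th percentile). Markers of other cells were higher too. Of 27 intestinal epithelium markers, 7 were higher, among them Cdh1 (3.96), Fabp1 (at least 3.08-fold) and Tff3 (at least 2.81-fold). Of 18 T and innate lymphoid cell markers, 6 were higher, among them Gzma (at least 37.2-fold), Cd3g (at least 13.3-fold) and Nkg7 (3.47). Of 18 macrophage and dendritic cell markers, 4 were higher, Itgax, C1qb (at least 4.28-fold), C1qa (1.86) and Csf1r (at least 2.71-fold). The medians of these 3 lists were 0.80, 0.84 and 0.63, each at the 100th percentile.

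In all, 569 genes were at least 2-fold higher and 857 lower among 12743 tested. Without the immediate early, feeder and other-cell lists, an alternative chosen after the data were seen, the numbers were 515 and 846. Tissue digestion, sorting and source differed together between these arrays.

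**Figure D2:**
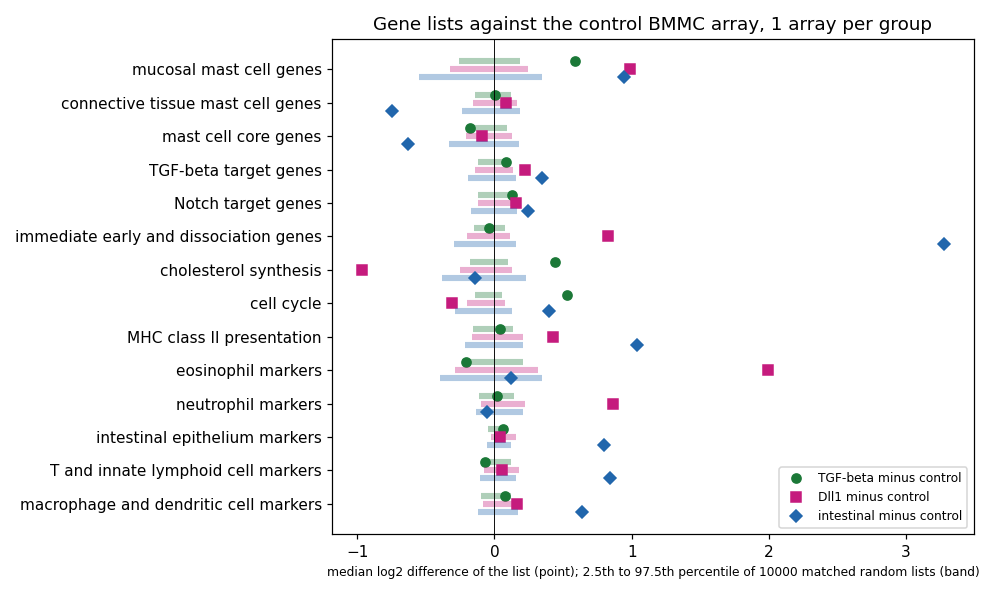
Median log2 difference (horizontal axis) of 14 gene lists (vertical axis) on the TGF-beta, Dll1 and intestinal arrays against the control array, with bands over the middle 95% of 10000 matched random lists. Immediate early genes lie at -0.042, 0.82 and 3.28, and cholesterol synthesis genes at 0.44, -0.97 and -0.14.

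The direct comparison of Dll1 with TGF-beta1 set one treatment against the other. Mcpt1 differed by 0.05 and Mcpt2 by -0.61 between the arrays, while Mcpt4 was at least 30.8-fold and Mcpt8 9.3-fold higher with Dll1. Mcpt1 read 12.41 with TGF-beta1 and 12.46 with Dll1, not far from the highest values, so saturation could hide a difference. Higher with Dll1 were also Prg2 (at least 75.8-fold), Fosb (at least 35.4-fold), Dusp1 (34.1-fold), Cd7 (at least 31.9-fold), Nr4a1 (25.2-fold), Atp1b1 (23.8-fold), Egr1 (23.2-fold), the integrin chain Itga4 (20.1-fold), the adhesion protein Emb (11.6-fold) and Dcaf5 (8.92-fold). Lower with Dll1 were Nrn1 (14.1-fold), Scd1 (7.78-fold), Neat1 (6.21-fold), Erv3 (5.83-fold), Mfsd2a (5.28-fold), Itga7 (4.82-fold), the proliferation marker Mki67 (4.63-fold) and Neb (4.58-fold). F13a1 was at least 11.6-fold, the proton channel Otop1 at least 10.2-fold, Mrgpra9 at least 9.08-fold and the transcription factor Eomes at least 3.86-fold lower. Tpsab1 was 3.39-fold lower and Hes1 2.22-fold higher with Dll1. A second probe set of Emb, near background, read 5.21 with Dll1 and 5.22 with TGF-beta1 and did not show its difference.

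Cholesterol synthesis genes were lower with Dll1 for 15 of 19, with a median of -1.23, and cell cycle genes for 13 of 38, with a median of -0.85, both below all random lists. Lss was lower by -1.91 and Insig1 by -1.87, and Cenpe was lower by -1.65 and Aurkb by -1.64. Immediate early genes were higher for 13 of 30, with a median of 0.78 (100th percentile). Eosinophil markers had a median of 1.97 and neutrophil markers one of 0.80, both at the 100th percentile. TGF-beta target genes had 2 of 29 higher and 2 lower with Dll1, with a median of 0.17 (98.6th percentile). With the mean of a gene's probe sets that median was 0.09 (87.5th percentile). In all, 278 genes were at least 2-fold higher and 240 lower among 12690 tested. With array medians subtracted the numbers were 247 and 297, and with the offset of 16 subtracted 434 and 403.

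The last comparison asked how far each treatment moved BMMCs in the direction of intestinal mast cells. Of the 569 genes higher in intestinal cells than in control BMMCs, 11 were higher with both treatments, 100 with Dll1 and not TGF-beta1, 18 with TGF-beta1 and not Dll1, and 440 (77.3%) with neither, by the 2-fold rule. Mcpt1, Mcpt2, Itgae, Plac8, Mcpt-ps1, Gadd45b and Sh2d1b1 were among the 11. Of the 857 lower genes, 22 were lower with both, 132 with Dll1 and not TGF-beta1, 48 with TGF-beta1 and not Dll1 and 655 (76.4%) with neither. A4galt, Serpinb2, Gbp4, Slc6a4, Cd59a and Mmp12 were among the 22. Mcpt4, Mcpt8 and Ctsg were higher with Dll1 and in intestinal cells but not with TGF-beta1. Tpsb2 and Cma1, 40.6-fold and 31.1-fold lower in intestinal cells, differed by less than 2-fold with either treatment.

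Dll1 shared 111 higher genes with the intestinal array, against 7.88 for independent lists, and 154 lower ones, against 15.9. TGF-beta1 shared 29 higher genes, against 2.32, and 70 lower ones, against 7.68. These counts share the control array, which raises them without any effect. The Dll1 and intestinal arrays also had in common a selection step and higher immediate early genes, 13 and 28 of 30. Without the immediate early, feeder and other-cell lists Dll1 shared 91 higher genes, against 6.34, and 150 lower ones, against 15.6. Over 13355 genes the log2 differences correlated at r = 0.55 between Dll1 minus control and intestinal minus control and at 0.44 for TGF-beta1. Simulated unchanged groups gave 0.50 for both, a value set by equal noise on every array and a shared control. The observed spreads, from the median absolute deviation, were unequal. They were 0.25 for TGF-beta minus control, 0.33 for Dll1 minus control and 0.46 for intestinal minus control. The simulated 0.50 is therefore no chance value for the observed correlations. The covariances were 0.198 and 0.113, against 0.032 simulated. The simulated noise had a standard deviation of 0.18 on every array, taken from the comparison with the smallest spread. The value of 0.032 follows from that choice, and wider noise would raise it. Without a shared array, r was 0.46 between Dll1 minus control and intestinal minus TGF-beta and 0.29 between TGF-beta minus control and intestinal minus Dll1. It was 0.23 between Dll1 minus TGF-beta and intestinal minus control. These correlations are across genes, which are not independent replicates, and the array for each group was single.

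**Figure D3:**
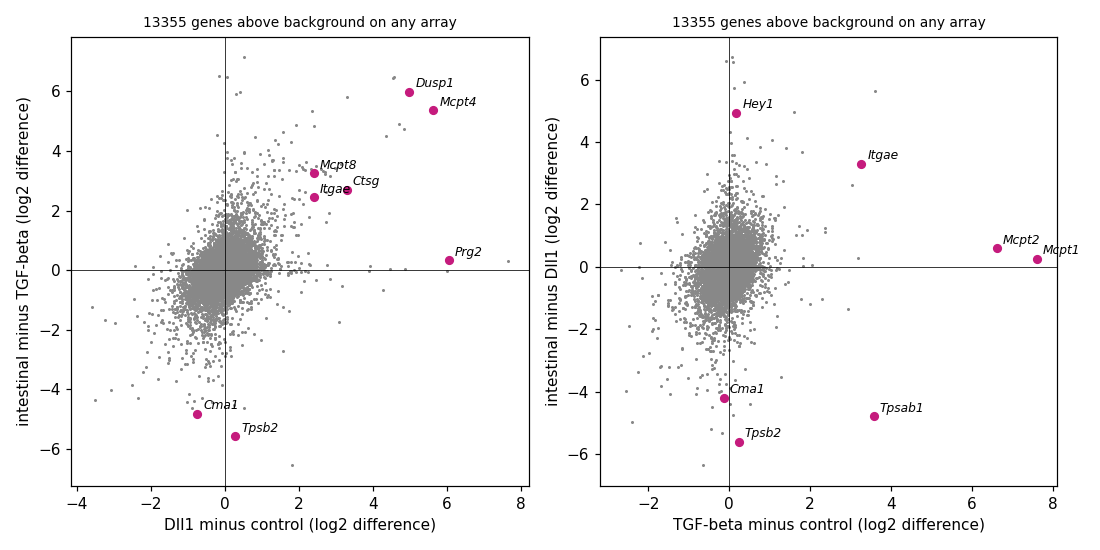
Log2 differences of 13355 genes, each a point, in pairs of comparisons that share no array, Dll1 minus control against intestinal minus TGF-beta (left) and TGF-beta minus control against intestinal minus Dll1 (right), with named genes in colour. The correlation is 0.46 on the left, where Mcpt4 and Dusp1 lie high on both axes, and 0.29 on the right.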

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

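All tests of explanations in this part were chosen after the pattern they address was seen. Only the test of granulocyte progenitors was written down before its own outcome was computed. The difference between treatments was not tested for any gene here, since each group had 1 array.

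At least 2-fold from control in opposite directions with the 2 treatments were 11 genes. Higher with Dll1 and lower with TGF-beta1 were Atp1b1 (Dll1 minus TGF-beta 4.58), Itga4 (4.33), Gfra2 (at least 3.48), Layn (2.67), Csf1 (2.59), Ccl3 (2.47), Itgb3 (2.41) and Gm2a (2.05). Lower with Dll1 and higher with TGF-beta1 were Nrn1 (-3.81) and, below background with Dll1 and so with bounds, Otop1 (-3.35 or lower) and F13a1 (-3.53 or lower). Among the 10272 probe sets without a single gene symbol, which the comparisons above did not use, 31 differed at least 2-fold from control with TGF-beta1, 143 with Dll1 and 299 in intestinal cells.

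Immediate early genes were higher on the Dll1 and intestinal arrays. A normalization between arrays that moves genes of 1 level alike would move this list no more than random lists matched on level. The list median of Dll1 minus control was 0.82, and the highest of 10000 such lists was 0.24. These are the random lists behind the 100th percentile given above, so this restates that percentile and is no separate test. The labels name a selection step for these 2 arrays alone, and the list median for TGF-beta1, with no such step named, was -0.042. Handling of the cells before lysis could therefore account for the pattern, but it goes with the groups and cannot be told apart from an effect of Dll1 or of the tissue.

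Some genes of eosinophil and neutrophil granules were higher on the Dll1 array, among them Prg2 (11.45 there), Prg3 (9.55) and Mpo. Other neutrophil granule genes did not pass 2-fold by the rule, although their measured values were higher than in control. They were Camp (1.16), Lcn2 (0.96), Ltf (0.77), Mmp8 (0.48) and Mmp9 (0.12), of which Camp, Lcn2 and Ltf were below background in control. The neutrophil marker Ly6g was lower with Dll1 (-1.05), and also with TGF-beta1 (-1.10) and in intestinal cells (-1.56). The 11 measured members of the eosinophil and neutrophil lists that had not passed 2-fold with Dll1 were also examined. Their medians were 0.17 for Dll1 minus control (89.86th percentile) and 0.34 for Dll1 minus TGF-beta (99.94th). They were what remained of the lists that showed the pattern, so their low medians say nothing about mature cells. None was clear of background by 1 (log2) on both arrays either. Mature neutrophils or eosinophils therefore stay open, although the cells were selected for c-Kit. A list of 16 granulocyte progenitor genes, written before its test, had a median of 0.65 (100th percentile), with Prtn3 (7.71), Ms4a3 (7.29) and Pglyrp1 (7.15) at least 2-fold higher and Ly6c2 lower. The values of Gfi1 and Ctsc in that list could be seen beforehand through other lists, and of the 5 members that far above background on both arrays, Serpinb1a (-0.90), Ly6c2 (-1.10) and Ctsc (-0.13) were lower and Gstm1 (0.52) and Cd24a (0.97) higher. Progenitors that carry c-Kit may have contributed, but the median rests mostly on members near background on the control array, and expression of granule genes by mast cells under Dll1 stays open and untested.

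Markers of other cells were higher on the intestinal array beside Itgax, Itgae and Cdh1. Among markers above background on both arrays, the largest difference was 1.82 (Muc2) for 6 epithelium markers beside Cdh1 (3.96), 1.86 (C1qa) for 8 macrophage and dendritic cell markers beside Itgax (at least 67.6-fold), and 3.47 (Nkg7) for 7 lymphoid markers beside Itgae (5.71). The remaining markers were below background on the control array, where a fold is a bound, such as Fabp1 (at least 3.08-fold), C1qb (at least 4.28-fold) and Gzma (at least 37.2-fold). Epithelial, myeloid and lymphoid cells therefore cannot be told apart from mast cells as the sources of these 3 genes on the intestinal array. In the BMMC cultures, which held no intestinal tissue, Itgae read 5.57 in control, 8.84 with TGF-beta1 and 7.97 with Dll1. Cdh1 read 6.16, 7.57 and 6.32 in the same order. A second Cdh1 probe set was below background on the BMMC arrays (4.64, 4.74 and 4.87) and read 5.84 on the intestinal array. Itgae was thus also raised in a culture, and so was Cdh1, but by the first probe set alone. Itgax stayed near background in the BMMC cultures. A small share of other cells may account for part of each, although the sort was for FceRI and c-Kit.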

How the results depend on the processing

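The alternatives that left out the handling, feeder and other-cell lists or subtracted an offset of 16 were chosen after seeing the data; the others were planned. No gene list outside the middle 95% of random lists, no always named gene past 2-fold and no correlation changed direction under its alternatives, but the balance of higher and lower genes did turn. For Dll1 minus TGF-beta it was 278 higher and 240 lower, 247 and 297 with array medians subtracted, and 796 and 913 at 1.5-fold. For Dll1 minus control it was 209 and 228, 216 and 211 after quantile normalization, and 51 and 17 at 4-fold. For TGF-beta minus control it was 61 and 107, and 12 and 9 at 4-fold. Subtracting array medians moved the median gene difference of Dll1 minus TGF-beta from 0.0165 to -0.0517, so that turn went with a uniform shift of all differences. The cause of the other turns was not tested. The number of genes at least 2-fold different was 168 for TGF-beta minus control, 437 for Dll1 minus control, 1426 for intestinal minus control and 518 for Dll1 minus TGF-beta. At 4-fold these became 21, 68, 349 and 80, and at 1.5-fold 785, 1585, 3204 and 1709, by construction of the threshold. With 16 subtracted from the linear values, as the floor above 4 would need, they were 295, 754, 2002 and 837. Array medians subtracted, quantile normalization, the other background limits, the mean of probe sets and the left-out lists kept each number within 1.5 times. Genes shared with the intestinal array at 4-fold were 31 higher and 17 lower for Dll1, and 6 higher and 7 lower for TGF-beta1. Of 164 list comparisons, 66 lay outside the middle 95% of random lists, and between 62 and 90 did so under the alternatives. Correlations moved by less than 0.1. Quantile normalization moved none of 76 differences of the always named genes by more than the spread between probe sets, and the mean of probe sets moved 2, those of Dll1 on its own array, which are bounds. Signal over background limits dim genes, whose folds are bounds. No paired analysis was possible because each group had 1 array.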

Other observations

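The genes named in this part were chosen after their values were seen, and no explanation was tested for them.

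The mast cell protease locus on chromosome 14 holds, in the order of the RefSeq table, Cma1, Mcpt-ps1, Cma2, Gm5801, Mcpt1, Mcpt2, Mcpt9, Mcpt4, Mcpt8, Ctsg and a row of granzymes that ends with Gzmb. With TGF-beta1, 3 of the 16 measured genes were at least 2-fold higher, Mcpt-ps1, Mcpt1 and Mcpt2. With Dll1, 6 were higher, the same genes with Mcpt4, Mcpt8 and Ctsg, which lie together. In intestinal cells 8 were higher, those 6 with Mcpt9 (7.08) and Gzmc (8.12), and Cma1 was lower. Gzmc was below background in control BMMCs (4.51) and read 6.08 with Dll1. Gzmd, Gzmg, Gzmn and Gzmf were below background on all 4 arrays. Gzmb stayed between 11.17 and 12.19. Near-identical sequences among these genes can share probes, which leaves the separate levels uncertain.

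Beyond the proteases, S1pr3, Homer2, Fermt2 and Il1b were higher on all 3 arrays against control. S1pr3, a receptor for sphingosine-1-phosphate, was 1.79 higher with TGF-beta1, 1.29 with Dll1 and 2.30 in intestinal cells, and Homer2 was 1.83, 1.71 and 1.99 higher. The B cell adaptor Blnk was lower by -1.42, -1.42 and -2.71, and the platelet glycoprotein gene Gp5 by -1.52, -2.20 and, as a bound, -2.71. Among type I interferon response genes, 5 of 25 were higher in intestinal cells, among them Oasl1 (2.48), Isg15 (2.25) and Ifih1 (1.79), and Usp18 (-1.23) was lower. The transcription factor Sox4 was above background on the Dll1 (6.90) and intestinal (8.14) arrays and below it on the other 2.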
